A study of Mus musculus with 12 samples.

How the data were processed

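Total RNA was sequenced from 4 female hybrid mouse embryonic stem cell (mESC) lines that carry a tamoxifen-inducible Cre at Rosa26. Lines 5.3 and 5.16 were Rif1+/+ and lines 15.10 and 16.9 carried floxed Rif1 on both alleles (Rif1F/F). Each line gave 1 library in each of 3 conditions: before deletion without 4-hydroxytamoxifen (OHT), as mESC after 2 days of OHT, and as embryoid bodies (EB) of 2 days after OHT. The 12 libraries therefore form 6 groups of 2. Rif1+/+ libraries are called WT, Rif1F/F libraries before OHT are called F/F, and Rif1F/F libraries after OHT are called KO. Titles of the F/F libraries carry both names, and the undeleted reading followed their bracketed part and the lack of OHT. Replicates 1 and 2 are lines 5.3 and 5.16, and replicates 3 and 4 are lines 15.10 and 16.9. Per the labels, mESC grew in serum with leukemia inhibitory factor and inhibitors of MEK and GSK3. The first part of the description label, read here as the flow cell, was the same within each condition and differed between conditions. Condition and flow cell cannot be told apart, whereas each genotype comparison lies within 1 flow cell. Differences between the 2 pairs of lines other than Rif1 cannot be told apart from genotype within a condition.

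The authors deposited whole-number read counts per gene symbol, without normalization, in 1 table of 24391 symbols. BWA, HTSeq and DESeq2 and the genome build mm9 are named in the submitters' processing notes, without versions or roles. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense genes such as Xist and Tsix may have been assigned to either. Each library's counts summed to between 28600870 and 64808897. A gene at 0 in a group was given a floor of 3 counts per library. Symbols were matched to a GRCm38 annotation by name: 23175 by RefSeq symbol, 685 by a unique synonym and 436 by GENCODE symbol, while 95 had no match. The annotation placed 1064 symbols on the X chromosome, 46 on the Y chromosome and 23185 on an autosome. It was used for chromosome, gene order, transcript GC content, length and shared 50-base words, and no coordinates are given because the builds differ.

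Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test on 1 model of the 6 groups with TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. The filter left 17115 genes, 679 of them X-linked and 16399 autosomal. The square root of the common dispersion was 0.0717 and the prior degrees of freedom 11.0. Standard errors (SE) of log2 fold changes come from the same fit, and levels are CPM of each library, mean ± SD over 2 libraries. The contrasts fixed before the data were examined compared genotypes within each condition, conditions within each genotype, and the genotype effects between conditions. Of these, 1 asked whether the genotype effect differed after OHT from that before it, and 1 whether it differed between EB and mESC. A further contrast set the genotype effect in EB against that before deletion and was added after the data were seen.

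25 gene lists were fixed before the data were examined. They cover core, naive and formative pluripotency, germ layers, primitive endoderm, trophoblast, two-cell-like, germline and imprinted genes. Others cover the X-inactivation centre, genes that escape X inactivation, Xist partners and Polycomb, and heterochromatin and KAP1 silencing. Replication licensing, double-strand-break repair, p53 targets, MAPK feedback, interferon response, cholesterol biosynthesis, glycolysis and clustered protocadherins were also listed, with feeder fibroblast markers as the other cell type the cultures might hold. The Y-linked list was only summed per library, giving 0 to 20 counts, and the list of mitochondrially encoded RNAs is not analysed here. The other 23 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. Of the 40 list calls at the preset correlation in the planned contrasts, 1 held with an estimated correlation, that of the formative and primed epiblast list in WT EB against WT mESC. Members were counted over all genes tested and with p adjusted over the list alone. X-linked genes were tested against other genes in the same way, adjusted over the contrasts.

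The genes named were chosen by a rule fixed with the lists. Rif1, Xist and Tsix were always named. For KO against WT after OHT, KO against WT in EB and the genotype by OHT difference, the 8 genes with the largest log2 fold change in each direction were taken among those with adjusted p under 0.05, a mean log2 CPM of at least 0 and, for the group comparisons, no overlap between the libraries of the groups. Each other contrast gave 5 per direction. Up to 4 members per list with the smallest adjusted p were added. The 5 Usp17l members shared 20.1% to 51.1% of their 50-base words with another gene, so the assignment of their reads to single copies is uncertain, whereas Pramel6 and Pramel7 shared 0% and 1.43%. Sharing was measured for two-cell-like genes only.

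Replicate numbers pair the libraries because the same number is the same cell line in each condition. The correlations of same-numbered libraries' deviations from their group means across genes were -0.07 for WT before deletion and after OHT, -0.06 for WT before deletion and EB, 0.03 for WT mESC and EB, 0.09 for F/F and KO after OHT, 0.03 for F/F and KO EB, and -0.00289 for KO mESC and EB. The fit without the block was the main one, and the fit with line as a block was run beside it. Other alternatives were DESeq2 size factors, no low-count filter, only the groups compared, the Wald test of DESeq2 1.42.0, limma voom with line as a random effect, and leaving out each library in turn. Chosen after the data were seen were taking out the GC trend of each library, with and without the block, leaving out Rn45s, Lars2 and Rpph1, rerunning the lists without WT mESC replicate 1 and, for the list tests, the block.

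The statistics were tested on simulated data, with counts drawn from the WT means of each condition and the real library sizes. The simulation held no genotype or line difference apart from the changes set in KO mESC, and 16745 genes passed the filter. For KO against WT after OHT, 79.1%, 89.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 14 of 16515 unchanged genes called. For the genotype by OHT difference the shares were 50.7%, 82.1% and 92.4%, again with 14 unchanged genes called. The changed genes had a mean log2 CPM of at least 0, so recovery of genes with fewer counts was not measured. Each gene had the same dispersion in all libraries, so a library that stands apart, as WT mESC replicate 1 does, was not simulated. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.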

Results

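RNA was measured in 12 libraries from 4 female mESC lines of a C57BL/6J-129/SvJ by Mus musculus castaneus cross, in which OHT activates Cre and removes floxed Rif1. RIF1 is a chromatin protein that controls replication timing and double-strand-break repair. Each of the 6 groups held 2 libraries: WT and F/F mESC before deletion, WT and KO mESC after 2 days of OHT, and WT and KO EB, in which mESC begin to differentiate and X inactivation starts. Total counts per library ranged from 28600870 to 64808897. Before deletion they were 37195345 and 34583317 in WT and 39816300 and 42000230 in F/F. After OHT they were 64808897 and 52351634 in WT mESC and 29505686 and 32848254 in KO mESC, and in EB 33655462 and 41862643 in WT and 36670852 and 28600870 in KO. Replicates correlated across genes at 0.993 to 0.995, although genes are not independent replicates. The first principal component held 58.4% of the variance, the next 16.5% and the one after 10.4%. WT mESC replicate 1 stood apart, with 0.869% of its counts in Lars2 against at most 0.140% in each other library, and a median histone gene level of 12.7 CPM against 31.0 to 67.3. Floors and intervals cover counting error only. Adjusted p-values are those of edgeR's quasi-likelihood test for genes and of camera for lists, and ± after a log2 fold change is its SE.

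The first question was whether OHT lowered Rif1 RNA in the Rif1F/F lines. Rif1 stood at 1530 ± 106 CPM in WT and 682 ± 28.7 CPM in KO mESC, a log2 fold change of -1.17 ± 0.08 (adjusted p = 4.4e-09), with both KO libraries under both WT libraries. In EB it was 1362 ± 28.0 CPM in WT and 817 ± 39.5 CPM in KO, a log2 fold change of -0.74 ± 0.08 (adjusted p = 6.7e-07). Before deletion it was already lower in the F/F lines, 1172 ± 0.161 CPM against 1644 ± 152 CPM, by -0.49 ± 0.08 (adjusted p = 7.4e-05). From before to after OHT, Rif1 fell in the Rif1F/F lines by 0.78 on the log2 scale (adjusted p = 8.8e-07), while in WT the change was -0.10 (adjusted p = 0.27) and 0.01 without WT pre-deletion replicate 2. The difference between those changes was -0.68 ± 0.11 (adjusted p = 9.8e-04). The counts cover the whole gene, so transcript that remains after the floxed part is removed is counted as Rif1.

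Xist, the RNA that coats and silences the inactive X chromosome, was higher in EB than in mESC and lower in KO than in WT EB. In WT it rose from 38.9 ± 5.32 CPM in mESC to 168 and 191 CPM in the 2 EB libraries, a log2 fold change of 2.21 ± 0.15 (adjusted p = 5.7e-10). In KO it rose from 25.9 ± 6.46 to 69.5 ± 3.29 CPM, by 1.42 ± 0.15 (adjusted p = 3.3e-07). Xist was lower in KO than in WT EB by -1.37 ± 0.14 (adjusted p = 8.1e-07) and lower in KO than in WT mESC by -0.58 ± 0.15 (adjusted p = 5.4e-03). The mESC difference was -0.35 (adjusted p = 0.129) without KO mESC replicate 4. Before deletion Xist was higher in F/F, 31.3 ± 5.51 against 19.4 ± 3.39 CPM, by 0.70 ± 0.15 (adjusted p = 1.8e-03).

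Tsix, the antisense repressor of Xist, was higher in F/F before deletion by 0.75 ± 0.17 (adjusted p = 2.4e-03) and in KO mESC by 0.67 ± 0.18 (adjusted p = 6.2e-03). The mESC value was 0.45 (adjusted p = 0.0622) without WT replicate 2 and 0.47 (adjusted p = 0.112) without KO replicate 3. In EB the Tsix difference was 0.41 ± 0.18 (adjusted p = 0.079), and it passed with no low-count filter (adjusted p = 0.0492) and with only the groups compared (adjusted p = 0.0255). Between the effects after and before OHT Tsix differed by -0.08 (adjusted p = 0.885) and between those in EB and mESC by -0.26 (adjusted p = 0.467). Xist and Tsix overlap on opposite strands, so reads of one may be counted for the other.

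**Figure D1:**
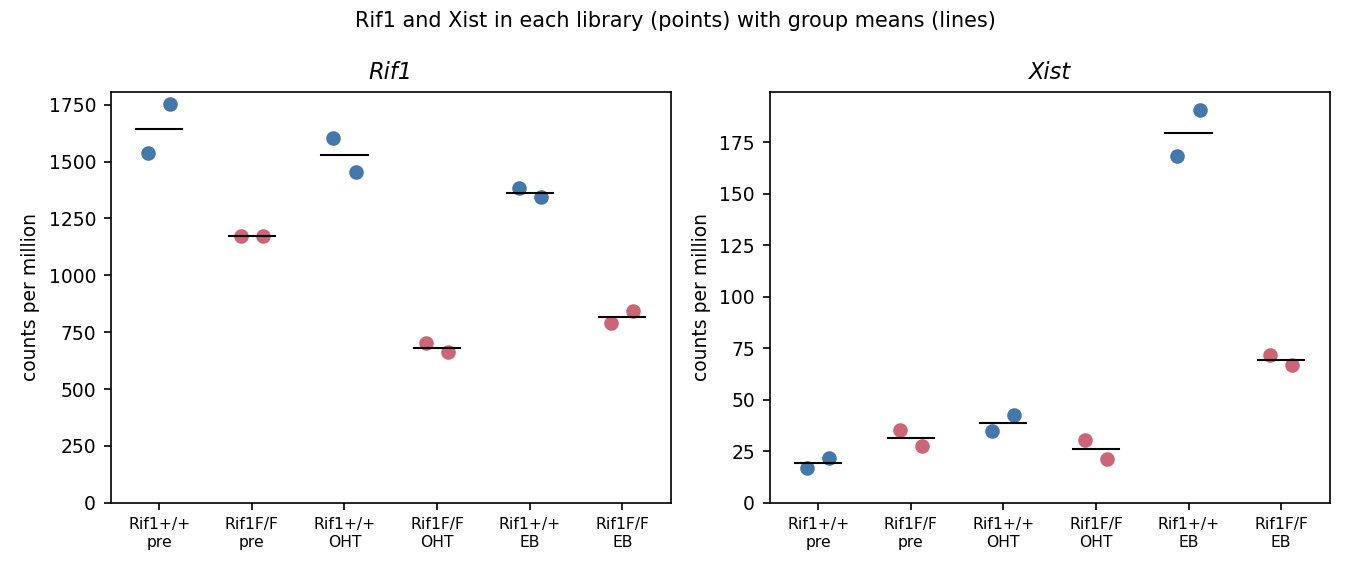
Rif1 and Xist in CPM for each of the 12 libraries by group, with points for libraries and lines for group means. Rif1 was lowest in KO mESC (682 CPM) and KO EB (817 CPM), and Xist was highest in the WT EB libraries (168 and 191 CPM).

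Comparing KO with WT mESC after OHT gives the genes that differed after OHT, many of which differed before it. Lincenc1, a long noncoding RNA of embryonic stem cells, stood at 134 ± 0.872 CPM in KO and 0.0684 ± 0.0423 CPM in WT mESC. Gata3, a transcription factor of trophoblast, was higher by 5.28 ± 0.22 on the log2 scale, and the neurofilament gene Nefm by 6.18 ± 0.32 (adjusted p = 1.7e-11 and 1.8e-10). Ephx2, which encodes soluble epoxide hydrolase, was higher by 4.12 ± 0.10 (adjusted p = 2.0e-14). Sytl3, a synaptotagmin-like gene, was lower at 1.90 ± 0.253 against 61.3 ± 1.48 CPM, and 4930548H24Rik was lower by -4.74 ± 0.16 (adjusted p = 1.1e-12). Olig2, a transcription factor of oligodendrocytes, stood at 20.0 ± 1.69 CPM in WT and 0.0154 CPM in KO, and 4930526L06Rik had no count in KO, at least 16.8-fold lower than the 1.61 ± 0.748 CPM of WT. Before OHT these genes were already apart, with F/F against WT at 7.92 for Lincenc1, 6.26 for Gata3, 5.67 for Nefm, 4.45 for Ephx2 and -4.41 for Sytl3, 4930548H24Rik at 51 against 660 counts, Olig2 at 0.0121 against 20.2 CPM, and 4930526L06Rik at no count in F/F against 1.21 CPM. In all, 3384 genes were higher and 3188 lower, 6572 of 17115 tested, with 938 and 758 by at least 2-fold. Without KO replicate 4 the number was 4125.

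Of the fixed lists, two-cell-like genes, active when the mouse embryo first turns on its genome, were higher in KO than in WT mESC, with 16 of 32 measured members higher and 1 lower, the same with p adjusted over the list alone. Their median log2 change was 1.72, or 1.63 with genes at 0 put at their bound (adjusted p = 1.4e-04, and adjusted p = 0.450 with an estimated correlation). Without WT replicate 1, 15 were higher and 1 lower, with a median of 2.61. Tmem92 stood at 3.19 ± 0.115 in KO against 0.292 ± 0.167 CPM in WT and Usp17le at 1.66 ± 0.0831 against 0.251 ± 0.109 CPM, and Gm13119 was higher by 2.90 ± 0.26. Germline genes were lower, 23 of 33 lower and 6 higher, the same over the list alone, with a median of -0.80 (adjusted p = 4.9e-05, and adjusted p = 0.450 with an estimated correlation). The synaptonemal complex gene Sycp1 stood at 7.91 in KO against 54.8 CPM in WT and Tex15, of meiotic recombination, at 17.3 against 93.0 CPM. In the F/F lines before OHT they stood at 3.71 and 8.58 CPM, so both were higher after OHT in these lines, by 1.09 and 1.01, and the tubulin gene Tuba3b was higher in KO than in WT by 2.59 ± 0.13, against 2.17 before OHT. Cholesterol biosynthesis genes were lower, 14 of 18 lower and 0 higher, the same over the list alone, with a median of -0.65 (adjusted p = 5.3e-06, and adjusted p = 0.450 with an estimated correlation). Dhcr7, of the last step of synthesis, was lower by -1.45 ± 0.10, and Msmo1 and Lss by -0.84 ± 0.07 and -0.83 ± 0.07. Imprinted genes were higher, 19 of 45 higher and 6 lower, or 20 and 6 when adjusted over the list alone, with a median of 0.30 (adjusted p = 0.0129, and adjusted p = 0.450 with an estimated correlation). Meg3, Rian and Rtl1, which share an imprinted cluster, were higher by 2.97 ± 0.11, 2.52 ± 0.09 and 2.66 ± 0.10. WT replicate 1, the library that stood apart, enters this comparison, and without it 22 germline, 13 cholesterol and 3 imprinted genes were lower and 6, 0 and 19 higher.

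The other lists did not pass in KO against WT mESC. Of 31 heterochromatin and KAP1 silencing genes 12 were lower and 1 higher, the same over the list alone (adjusted p = 0.0637). DNA methylation genes were among them, with Dnmt3l lower by -0.79 ± 0.06 and Dnmt3b by -0.60 ± 0.07, and the chromatin remodeller Hells by -0.64 ± 0.07. Dnmt3l was already lower in F/F before OHT, by -0.48. Higher and lower counts were 5 and 4 of 14 core pluripotency genes, 9 and 5 of 25 naive, 4 and 5 of 22 formative, 8 and 4 of 21 primitive endoderm and 6 and 1 of 13 trophoblast genes. Of these, adjusted over the list alone, the primitive endoderm count was 10 and 4 and the others the same. They were 3 and 5 of 18 mesendoderm (3 and 6 adjusted over the list alone), 2 and 4 of 13 neuroectoderm, 3 and 3 of 14 X-inactivation centre and 2 and 5 of 17 escape genes, the last 3 the same over the list alone. Phf19, a Polycomb partner, was lower by -2.94 ± 0.18, and by -2.12 already before OHT. It was among 13 lower and 10 higher of 37 Xist partners and Polycomb genes (the same over the list alone), and 15 of 34 replication genes were lower and 5 higher, 16 and 5 adjusted over the list alone. Further counts were 4 and 6 of 22 double-strand-break repair genes (4 and 7 adjusted over the list alone), 2 and 11 of 30 p53 targets and 4 and 10 of 23 MAPK feedback genes (both the same over the list alone), 5 and 6 of 24 interferon genes (5 and 7 over the list alone) and 5 and 2 of 22 glycolysis genes (the same). Feeder fibroblast markers counted 6 and 2 of 16, 7 and 2 adjusted over the list alone, and clustered protocadherins 3 and 0 of 23, none adjusted over the list alone. The medians and means differed in sign for formative (0.04 and -0.09), Polycomb (0.05 and -0.01) and interferon genes (0.02 and -0.35), for which camera ran negative. These medians were -0.003, 0.08 and 0.21 without WT replicate 1. The fit without that library filtered the genes anew, so it measured 19 mesendoderm and 18 feeder genes. Without WT replicate 1, which stood apart, 5 replication genes were lower and 3 higher, and 7 heterochromatin genes were lower and 1 higher (adjusted p = 0.213). Higher and lower counts were then 2 and 3 core pluripotency, 2 and 5 formative, 3 and 3 mesendoderm, 4 and 1 trophoblast, 2 and 2 escape, 7 and 7 Polycomb, 4 and 3 repair, 3 and 9 p53, 2 and 10 MAPK, 6 and 3 feeder, 2 and 0 protocadherin and 3 and 2 glycolysis genes.

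Comparing KO with WT EB asked how differentiation and X inactivation proceed in the floxed lines after OHT. Two-cell-like genes were higher in KO than in WT EB in 31 of 32 measured members, and lower in 0, the same when adjusted over the list alone. Their median log2 change was 4.37 (adjusted p = 4.9e-20, and adjusted p = 0.108 with an estimated correlation). Usp17lb stood at 49.3 ± 0.44 in KO against 1.14 ± 0.0217 CPM in WT, Usp17le at 54.3 ± 5.08 against 2.51 ± 0.0279 CPM and Tmem92 at 55.4 ± 3.54 against 1.68 ± 0.194 CPM. Gm13119, a Pramel family member, was higher by 4.37 ± 0.16. Outside the list, Atp4b, a subunit of the gastric proton pump, was at 69.5 ± 8.58 against 0.0794 ± 0.0265 CPM and Prr18 at 25.3 ± 1.06 against 0.338 CPM, whereas before OHT they differed by -0.39 (adjusted p = 0.276) and -0.79. Lincenc1 was again higher, at 128 ± 2.81 against 0.266 ± 0.0753 CPM, and 4930548H24Rik and the FGF co-receptor gene Klb lower by -6.70 ± 0.14 and -4.05 ± 0.14. 4930526L06Rik had no count in KO EB, at least 51.8-fold lower than the 4.74 ± 0.231 CPM of WT. Before OHT Lincenc1 and Klb already differed by 7.92 and -3.38, 4930548H24Rik had 51 counts in F/F against 660 in WT, and 4930526L06Rik had no count in F/F against 1.21 CPM in WT. In all, 3542 genes were higher and 3372 lower, 6914 in sum, with 1156 and 973 by at least 2-fold.

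Formative and primed epiblast genes, which mark exit from the naive state, were lower in KO than in WT EB, 17 of 22 lower and 3 higher, the same over the list alone, with a median of -0.58 (adjusted p = 3.1e-04, and adjusted p = 0.108 with an estimated correlation). The de novo methyltransferase Dnmt3a stood at 387 ± 6.40 against 986 ± 13.9 CPM and the transcription factor Otx2 at 78.2 ± 0.194 against 179 ± 20.5 CPM, and Sall2 was lower by -1.36 ± 0.09. Naive pluripotency genes were higher, 15 of 25 higher and 5 lower, or 16 and 8 when adjusted over the list alone, with a median of 0.35 (adjusted p = 0.0362, and adjusted p = 0.588 with an estimated correlation). Fbxo15 was at 358 ± 9.4 against 103 ± 10.8 CPM and Nanog, a core naive factor, at 160 ± 1.99 against 73.7 ± 8.45 CPM. Zfp42 was higher by 1.27 ± 0.09, and had already been higher in the Rif1F/F lines by 0.80 before OHT and by 1.32 in mESC after it. Cholesterol biosynthesis genes were lower, 16 of 18 lower and 0 higher, the same over the list alone, with a median of -0.69 (adjusted p = 2.5e-07, and adjusted p = 0.373 with an estimated correlation), among them Lss by -1.17 ± 0.07 and Msmo1 by -1.11 ± 0.07. Heterochromatin and KAP1 silencing genes were lower, 13 of 31 lower and 2 higher, the same over the list alone, with a median of -0.12 (adjusted p = 0.0362, and adjusted p = 0.533 with an estimated correlation), with Dnmt3b lower by -0.65 and Hells by -0.63.

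The other lists did not pass in EB. Trophoblast genes had 4 higher and 1 lower of 13 (adjusted p = 0.0653), with Gata3 higher by 3.85 and Tfap2c by 1.43. Core pluripotency genes had 7 lower and 2 higher of 14 (adjusted p = 0.0653), and MAPK feedback genes, which report ERK signalling, 14 lower and 3 higher of 23 (adjusted p = 0.0936), with Dusp6 lower by -0.90 and the X-linked ubiquitin ligase adaptor Klhl13 higher by 1.49 ± 0.07. Germline genes split, 13 higher and 17 lower of 33, with a median of -0.38 and a mean of 0.15. Among them Pet2 was higher by 5.45 ± 0.18 and Tdrd12, of the piRNA pathway, lower by -1.30. The X-inactivation centre had 2 higher and 7 lower of 14 and escape genes 1 and 5 of 17, with the Xist activator gene Rlim higher by 0.69 ± 0.06 and the noncoding RNA Ftx lower by -0.80. In all of these lists the counts were the same when adjusted over the list alone. Higher and lower counts were 9 and 12 of 45 imprinted, 5 and 2 of 18 mesendoderm, 4 and 7 of 21 primitive endoderm, 1 and 1 of 13 neuroectoderm, 4 and 5 of 37 Polycomb, 2 and 2 of 22 repair, 7 and 4 of 30 p53, 7 and 3 of 16 feeder, 7 and 0 of 23 protocadherin and 6 and 2 of 22 glycolysis genes, again the same over the list alone. Replication genes had 4 higher and 12 lower of 34, or 5 and 12 adjusted over the list alone, and interferon genes 7 and 4 of 24, or 11 and 5. Median and mean differed in sign for neuroectoderm (0.10 and -0.06), repair (-0.02 and 0.03) and glycolysis genes (0.00 and -0.05).

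**Figure D2:**
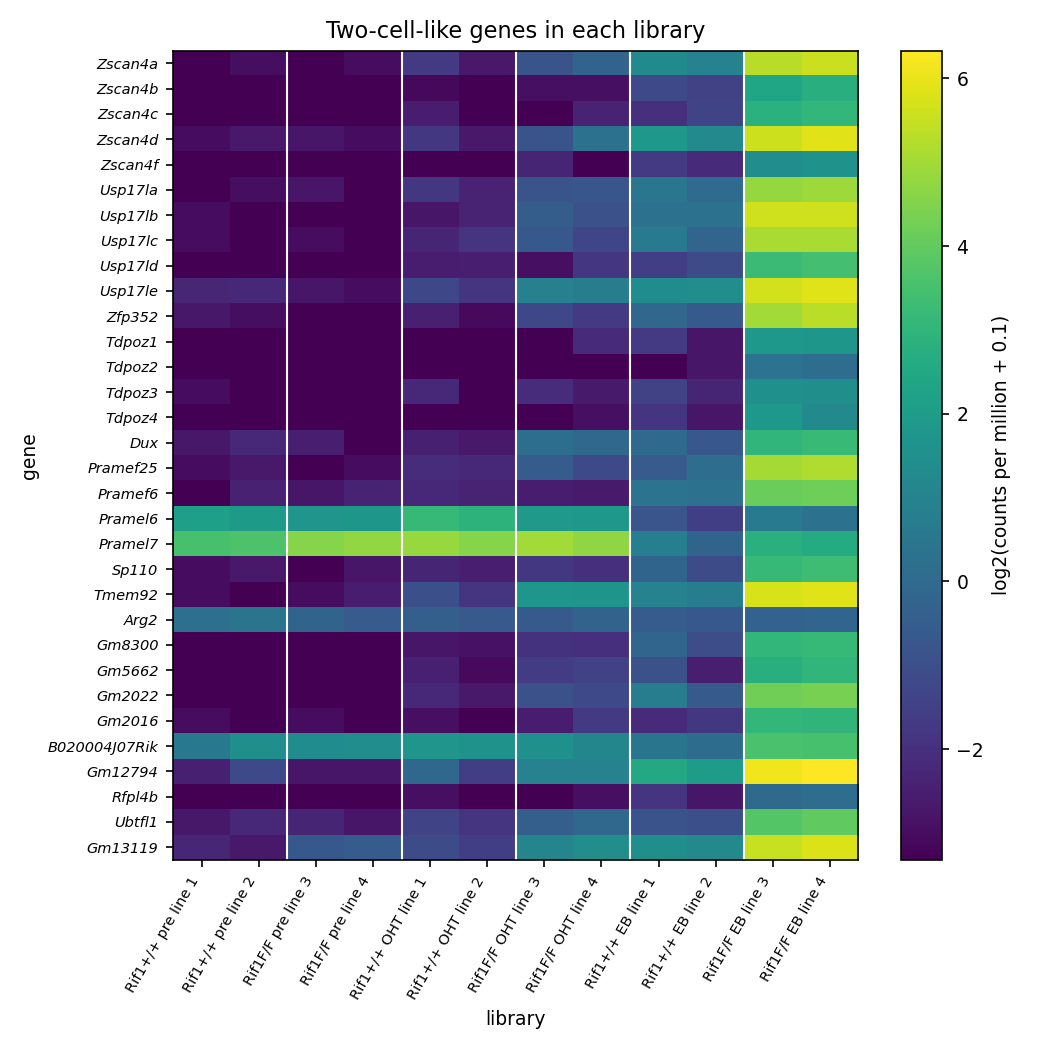
Heat map of log2 (CPM + 0.1) for the 32 measured two-cell-like genes (rows) in the 12 libraries (columns) by group. In 29 of the 32 genes both KO EB libraries stood above every KO mESC and WT EB library, for example Tmem92 at 55.4 ± 3.54 CPM.

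X-linked genes as a group were higher in KO than in WT EB. Their median log2 fold change lay 0.34 above that of autosomal genes (adjusted p = 9.3e-12, and adjusted p = 0.0747 with an estimated correlation), with 320 of 679 higher and 49 lower. X-linked counts were 5.51 ± 0.0724% of autosomal counts in KO EB and 4.57 ± 0.121% in WT EB, and the ratio of X-linked to autosomal median levels was 1.04 ± 0.00678 against 0.723 ± 0.0302. For KO against WT mESC after OHT the X-linked minus autosomal median was 0.02 (adjusted p = 0.70), with 153 higher and 119 lower. It was -0.02 without KO replicate 3. Before deletion X-linked genes were lower in F/F by -0.11 (adjusted p = 0.0065, and adjusted p = 0.36 with an estimated correlation), with 106 higher and 201 lower.

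**Figure D3:**
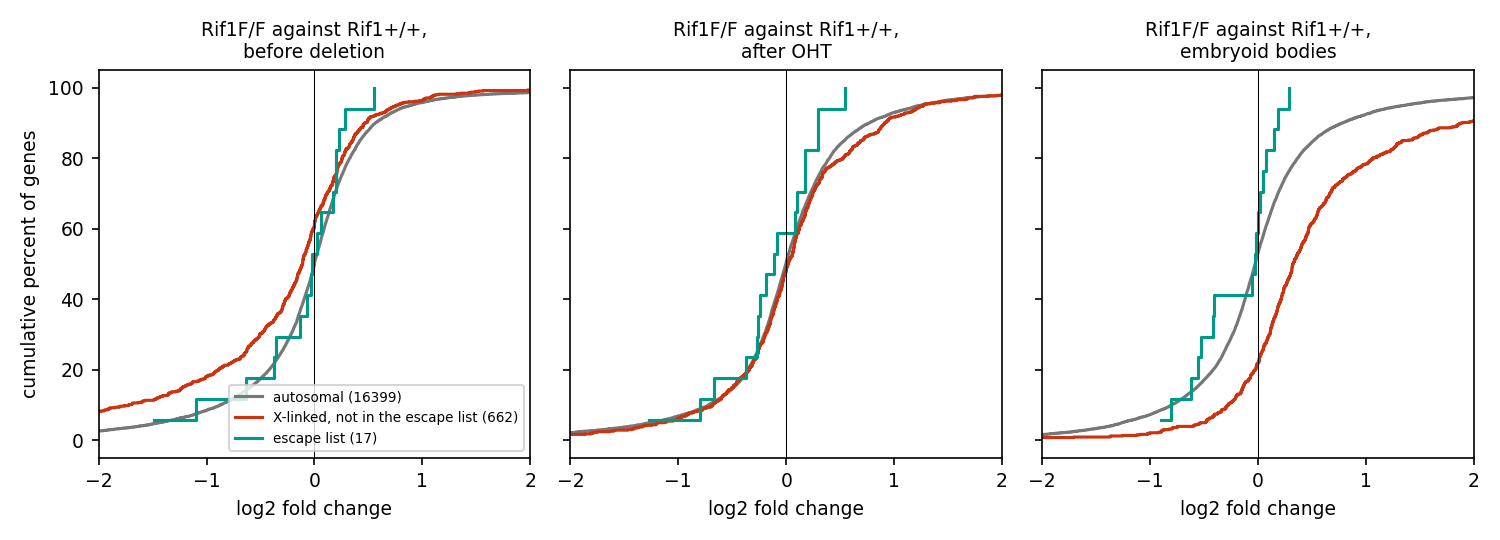
Cumulative percent of genes against log2 fold change for 16399 autosomal genes, 662 X-linked genes outside the escape list and 17 escape genes, in the 3 genotype comparisons. In EB the curve of the other X-linked genes lies to the right of the autosomal curve, by a median of 0.34 for all X-linked genes, while the escape genes had a median of -0.03.

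Before OHT the F/F lines were compared with the WT lines, and Rif1 was already lower in F/F, by -0.49. Germline genes were lower in F/F lines, 27 of 33 lower and 1 higher, the same over the list alone, with a median of -1.32 (adjusted p = 1.8e-14, and adjusted p = 0.382 with an estimated correlation). Sycp1 stood at 3.71 ± 0.844 against 71.8 ± 1.74 CPM and the germ cell RNA-binding gene Dazl at 91.0 ± 8.57 against 662 ± 27.8 CPM. Cholesterol genes were lower, 16 of 18 lower and 0 higher, the same over the list alone, with a median of -0.58 (adjusted p = 1.1e-07, and adjusted p = 0.382 with an estimated correlation). Dhcr7 was at 33.1 ± 0.327 against 113 ± 15.4 CPM. Imprinted genes were higher, 15 of 45 higher and 6 lower, the same over the list alone, with a median of 0.15 (adjusted p = 0.0420, and adjusted p = 0.382 with an estimated correlation), Meg3 being higher by 2.44 ± 0.10. This imprinted call ended with the GC trend taken out (adjusted p = 0.0751). Two-cell-like genes had 2 higher and 0 lower of 32, the same over the list alone. Lincenc1 and Gata3 were higher by 7.92 ± 0.12 and 6.26, Pxt1 had no count in F/F, at least 42.9-fold lower, and Col1a2 none in WT, at least 12.3-fold higher in F/F. Col1a2 is a feeder fibroblast marker, and of the 16 on that list 3 were higher and 1 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.987). The others, looked up after the count was seen, were Col6a1 (4.09) and Col1a1 (0.74), higher, and Thy1 (-2.70), lower. In all, 3402 genes were higher and 2992 lower, 6394 in sum.

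Much of the difference after OHT was present before deletion. Of the 6572 genes called between KO and WT mESC, 3637 (55.3%) were called in the same direction before deletion, as were 2250 (32.5%) of the 6914 called in EB. After OHT these were 1916 higher and 1721 lower, against 672.6 and 557.3 for independent lists, and in EB 1175 and 1075, against 704.1 and 589.5. Across genes, which are not independent replicates, the log2 fold change before deletion correlated with that after OHT at r = 0.60 (rho = 0.57) and with that in EB at r = 0.22 (rho = 0.23). These comparisons share no libraries but use the same 4 lines. Genes called both before deletion and after OHT numbered 3767, with 96.5% in the same direction. Of the 6572 genes, 846 were called in the genotype by OHT difference, 663 of them in the direction of their KO against WT difference. A gene not called before deletion need not have changed with OHT. The test of the difference also recovered fewer small changes in the simulation. The difference between the genotype effects in EB and before deletion, added after the data were seen, was called for 5339 genes, 2652 higher and 2687 lower. Of the 6914 genes called in EB, 3412 were called in this difference, 3153 of them in the direction of their KO against WT difference. X-linked genes lay 0.45 above autosomal genes in it, 284 higher and 36 lower (adjusted p = 6.7e-13, and adjusted p = 0.0747 with an estimated correlation). By that measure 11 two-cell-like genes were higher and 0 lower, or 13 and 0 when adjusted over the list alone (adjusted p = 5.5e-19, and adjusted p = 0.144 with an estimated correlation). Germline genes had 25 higher and 5 lower, the same over the list alone (adjusted p = 1.2e-08, and adjusted p = 0.281 with an estimated correlation).

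**Figure D4:**
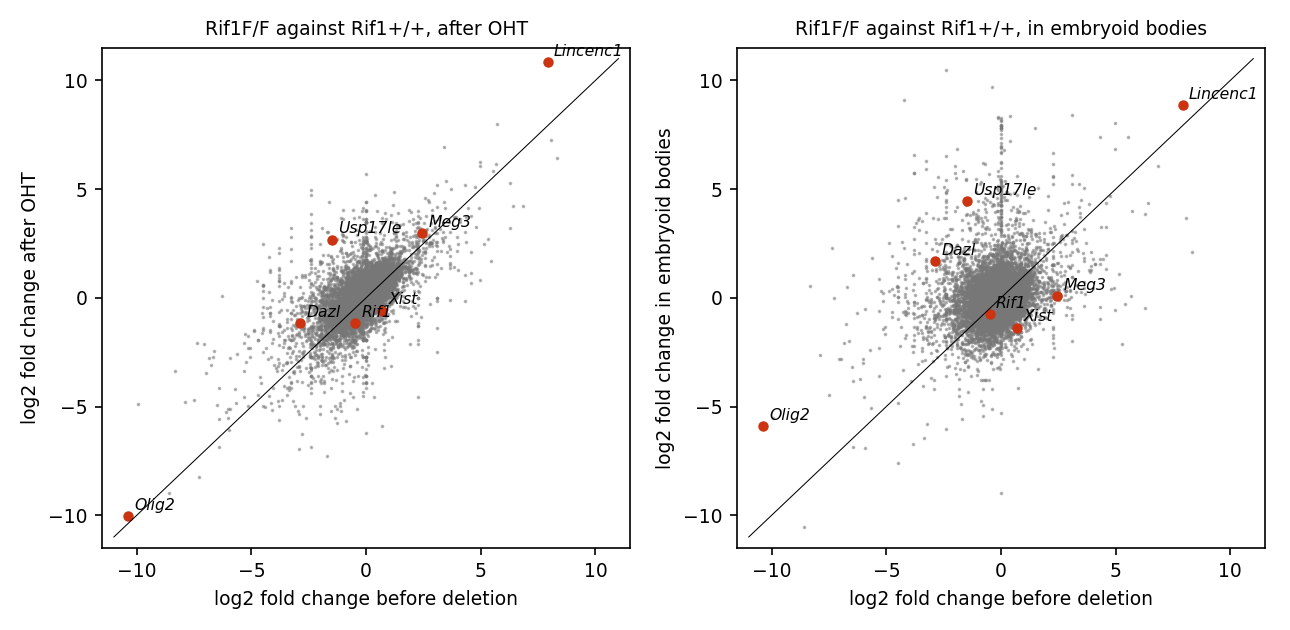
Log2 fold change between the Rif1F/F and WT lines before deletion (x axis) against that after OHT in mESC and in EB (y axes), 1 point per gene with some genes labelled. Genes lie along the diagonal more closely after OHT (r = 0.60) than in EB (r = 0.22).

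Setting the genotype effect after OHT against that before it asks which differences changed with OHT. A value here is a difference between 2 differences, so a negative one does not mean that the gene went down. Germline genes were higher by this measure, 20 of 33 higher and 3 lower, or 24 and 5 when adjusted over the list alone, with a median of 0.81 (adjusted p = 6.1e-10, and adjusted p = 0.426 with an estimated correlation). Dazl was higher by 1.69 ± 0.12, the testis ADP/ATP carrier Slc25a31 by 3.82 ± 0.26, the piRNA gene Asz1 by 3.38 ± 0.25 and the germ cell factor Sohlh2 by 1.74 ± 0.14. The X-linked homeobox gene Rhox13 was higher by 3.87 ± 0.27 (adjusted p = 3.3e-07), and 2610035D17Rik and Onecut2 were lower by -2.20 and -2.28. Two-cell-like genes were called both ways, 2 higher and 2 lower of 32, or 4 and 2 adjusted over the list alone, while the list test passed upward with a median of 1.79, or 0.91 with genes at 0 at their bound (adjusted p = 5.7e-06, and adjusted p = 0.426 with an estimated correlation). Heterochromatin and KAP1 silencing genes were lower by this measure, 7 of 31 lower and 0 higher, or 12 and 0 adjusted over the list alone, with a median of -0.20 (adjusted p = 0.0025, and adjusted p = 0.426 with an estimated correlation), Cbx5, encoding HP1 alpha, by -0.51 ± 0.10. Of these genes 11 were higher and 5 lower from F/F to KO mESC, and 18 higher and 4 lower from before to after OHT in WT. Without WT mESC replicate 1, which stood apart, 2 heterochromatin genes were lower (adjusted p = 0.0110) and 3 two-cell-like genes higher and 1 lower. X-linked genes lay 0.12 above autosomal genes (adjusted p = 9.2e-05, and adjusted p = 0.24 with an estimated correlation), or 0.19 with the GC trend taken out, and Xist was lower by -1.28 ± 0.22 (adjusted p = 1.8e-03). In all, 697 genes were higher and 649 lower, 1346 in sum, 364 and 45 of them by at least 2-fold. That number was 705 with only the groups compared, 63.1% of them higher against 51.8%, and 2218 with no low-count filter. It was 510 without WT pre-deletion replicate 1, 633 without F/F replicate 4, 831 and 2540 without WT mESC replicates 1 and 2, and 604 and 592 without KO mESC replicates 3 and 4.

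From mESC to EB, naive genes fell and formative genes rose in both genotypes. In WT, 22 of 25 naive genes were lower and 3 higher, with a median of -1.69 (adjusted p = 3.9e-09, and adjusted p = 0.131 with an estimated correlation), Tfcp2l1 by -4.30 ± 0.09. Formative genes had 19 of 22 higher and 2 lower, with a median of 2.44 (adjusted p = 3.7e-08, and adjusted p = 0.0378 with an estimated correlation), Fgf5 going from 0.218 to 67.1 ± 0.509 CPM. MAPK feedback genes rose, 18 of 23 higher and 3 lower (adjusted p = 0.0017, and adjusted p = 0.0885 with an estimated correlation), Spry4 by 6.54, and so did the X-inactivation centre, 9 of 14 higher and 2 lower (adjusted p = 0.0131, and adjusted p = 0.400 with an estimated correlation), Ftx by 2.47. These counts were the same over the list alone. Two-cell-like genes rose, 24 of 32 higher and 3 lower, or 26 and 3 adjusted over the list alone (adjusted p = 1.9e-04, and adjusted p = 0.400 with an estimated correlation), with a median of 3.00, or 2.62 with genes at 0 at their bound, and imprinted genes, 29 of 45 higher and 8 lower, or 29 and 9 over the list alone (adjusted p = 8.9e-04, and adjusted p = 0.127 with an estimated correlation). Feeder fibroblast markers had 9 higher and 2 lower (adjusted p = 0.0549), and passed with the line as a block (adjusted p = 0.0440). Without WT mESC replicate 1 their median was 1.21, over the 18 members measured in that fit. In all, 5554 genes were higher and 5107 lower. X-linked genes lay -0.17 from autosomal genes (adjusted p = 0.12). Rif1 differed by -0.17 (adjusted p = 0.062), and passed without WT mESC replicate 2 (-0.24, adjusted p = 0.0150), in DESeq2 (adjusted p = 0.0328), with no low-count filter (adjusted p = 0.0207) and with the GC trend taken out (adjusted p = 0.0285).

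In KO, 20 of 25 naive genes were lower and 4 higher, or 20 and 5 when adjusted over the list alone, with a median of -1.66 (adjusted p = 3.7e-07, and adjusted p = 0.192 with an estimated correlation), Tfcp2l1 by -3.97. Formative genes had 18 of 22 higher and 3 lower, the same over the list alone, with a median of 1.35 (adjusted p = 1.2e-05, and adjusted p = 0.106 with an estimated correlation), Fgf5 by 8.49. Two-cell-like genes rose, 29 of 32 higher and 2 lower, the same over the list alone, with a median of 5.71, or 5.68 with genes at 0 at their bound (adjusted p = 8.6e-11, and adjusted p = 0.164 with an estimated correlation), Usp17le by 5.03. Germline genes rose, 23 of 33 higher and 3 lower, or 23 and 5 over the list alone (adjusted p = 3.0e-04, and adjusted p = 0.355 with an estimated correlation), and p53 targets, 20 of 30 higher and 4 lower (adjusted p = 0.0079, and adjusted p = 0.355 with an estimated correlation), Plk3 by 2.48 against 2.58 in WT. Interferon genes rose, 13 of 24 higher and 4 lower (adjusted p = 0.0180, and adjusted p = 0.234 with an estimated correlation), MAPK feedback genes, 13 of 23 higher and 3 lower (adjusted p = 0.0112, and adjusted p = 0.164 with an estimated correlation), and imprinted genes, 25 of 45 higher and 7 lower, or 26 and 7 over the list alone (adjusted p = 0.0112, and adjusted p = 0.192 with an estimated correlation). X-linked genes lay 0.27 above autosomal genes (adjusted p = 0.0065, and adjusted p = 0.36 with an estimated correlation). Rif1 was higher by 0.26 (adjusted p = 0.0067), with adjusted p = 0.0840 without KO mESC replicate 4, adjusted p = 0.0871 without KO EB replicate 4 and adjusted p = 0.0788 with the GC trend taken out. In all, 5371 genes were higher and 4729 lower. The p53, interferon and MAPK counts were the same over the list alone. From mESC to EB in WT, the p53 and interferon medians were 0.29 and 1.01 without WT mESC replicate 1, so these rises were not seen in KO alone. Condition and flow cell cannot be told apart in the mESC to EB comparisons.

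The difference between these changes was tested directly. A value here is a difference between 2 changes, so its sign does not give the direction of change in either genotype. The two-cell-like list, for example, holds Pramel6 and Pramel7, which fell from mESC to EB in WT by -4.52 and -4.49. By this measure two-cell-like genes were higher, 18 of 32 higher and 0 lower, or 22 and 0 when adjusted over the list alone, with a median of 2.73, or 3.09 with genes at 0 at their bound (adjusted p = 8.4e-15, and adjusted p = 0.197 with an estimated correlation). Without WT mESC replicate 1, which stood apart, 9 were higher, with a median of 1.49. Germline genes were also higher by this measure, 18 of 33 higher and 4 lower, or 20 and 4 over the list alone, with a median of 0.68 (adjusted p = 1.4e-04, and adjusted p = 0.591 with an estimated correlation), Dazl by 2.86 ± 0.12. In WT, Dazl fell from mESC to EB by -2.94. Formative genes rose less, 11 of 22 lower and 1 higher, or 13 and 3 over the list alone, with a median of -0.61 (adjusted p = 0.0027, and adjusted p = 0.197 with an estimated correlation), Sall2 by -1.68 and Dnmt3a by -0.77. Imprinted genes were lower by this measure, 15 of 45 lower and 7 higher, the same over the list alone, with a median of -0.19, or -0.33 with genes at 0 at their bound (adjusted p = 0.0432, and adjusted p = 0.453 with an estimated correlation), Meg3 by -2.90. The imprinted list rose from mESC to EB in both genotypes, and Meg3 rose by 4.03 in WT. X-linked genes lay 0.35 above autosomal genes (adjusted p = 2.5e-09, and adjusted p = 0.0855 with an estimated correlation), with 247 of 679 higher and 33 lower. The X-linked gene 4930550L24Rik was higher by 5.32 ± 0.13, at 194 ± 10.5 CPM in KO and 4.13 ± 0.503 CPM in WT EB. Xist rose less in KO, by -0.79 ± 0.21 (adjusted p = 9.0e-03), a difference that was -0.51 without KO mESC replicate 3 (adjusted p = 0.0820) and missed the threshold in DESeq2 (adjusted p = 0.0507). Rif1 differed by 0.43 ± 0.11 (adjusted p = 6.3e-03), or 0.27 with the GC trend taken out. In all, 2541 genes were higher and 2348 lower.

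OHT was given to both genotypes, so the change from before to after it includes the drug, the time and the flow cell. In WT, replication genes rose, 23 of 34 higher and 1 lower, or 26 and 2 when adjusted over the list alone, with a median of 0.28 (adjusted p = 2.7e-04, and adjusted p = 0.758 with an estimated correlation), the licensing genes Mcm5 and Mcm7 by 0.61 and 0.54. Heterochromatin genes rose, 18 of 31 higher and 4 lower, or 19 and 4 over the list alone (adjusted p = 0.0025, and adjusted p = 0.758 with an estimated correlation), Dnmt3l by 1.30, and core pluripotency genes, 10 of 14 higher and 2 lower, the same over the list alone (adjusted p = 0.0117, and adjusted p = 0.758 with an estimated correlation), L1td1 by 1.00. Two-cell-like genes rose, 12 of 32 higher and 1 lower, or 9 and 1 over the list alone, with a median of 1.52, or 0.82 with genes at 0 at their bound (adjusted p = 0.0063, and adjusted p = 0.758 with an estimated correlation). Without WT mESC replicate 1, which stood apart, this call ended, with 4 higher and 1 lower and a median of 0.78 (adjusted p = 0.0702), and heterochromatin genes had 16 higher and 2 lower and core pluripotency genes 9 and 1. In all, 4264 genes were higher and 4138 lower. Xist rose by 1.01 ± 0.15 in WT (adjusted p = 5.4e-05).

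In the Rif1F/F lines, two-cell-like genes rose, 19 of 32 higher and 0 lower, or 20 and 0 when adjusted over the list alone, with a median of 4.23, or 1.86 with genes at 0 at their bound (adjusted p = 1.4e-07, and adjusted p = 0.910 with an estimated correlation). Usp17lb had no count before deletion and was at least 7.27-fold higher after it. Germline genes rose, 21 of 33 higher and 8 lower, the same over the list alone, with a median of 0.96 (adjusted p = 6.7e-04, and adjusted p = 0.910 with an estimated correlation), Dazl by 1.66 and Sohlh2 by 1.53. Glycolysis genes rose, 12 of 22 higher and 3 lower, the same over the list alone, with a median of 0.26 (adjusted p = 0.0370, and adjusted p = 0.910 with an estimated correlation), Ldha by 1.11 and Pkm by 0.90. In WT, Ldha and Pkm rose by 1.20 and 0.91, and the glycolysis median was 0.33 without WT mESC replicate 1, so the rise was not particular to the Rif1F/F lines. With the GC trend taken out, adjusted p for glycolysis in the Rif1F/F lines was 0.0787 without and 0.0426 with the line as a block. Xist differed by -0.28 (adjusted p = 0.156), and by -0.28 with the line as a block (adjusted p = 0.0240) and -0.55 without KO replicate 3 (adjusted p = 0.0187). In all, 3790 genes were higher and 3683 lower.

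The differences between KO and WT in mESC and in EB were compared across genes, which are not independent replicates. The log2 fold changes correlated at r = 0.43 (rho = 0.33), or r = 0.256 with no low-count filter, and 3297 genes were called in both, 78.7% in the same direction. Of these, 1374 were higher in both against 700.3 for independent lists, 1222 lower in both against 628.1, and 701 opposite. The log2 fold changes from mESC to EB correlated at r = 0.75 (rho = 0.71) between WT and KO. These pairs of comparisons share no libraries, but the KO and WT differences come from the same 4 lines and the changes from mESC to EB from the same flow cells, and the numbers for independent lists do not take this into account.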

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

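The tests of partial deletion (4 versions, 3 of them added once the first was seen to depend on how genes were picked), of slower exit from the naive state, of X chromosome loss, of shared reads, of a line difference present before deletion and of the difference between the EB and pre-deletion effects were chosen after the result was seen, whereas those of autosome gain or loss, of strain segments and of GC content, length and expression were fixed before it.

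The genotype effect differed between conditions for 13 results, each by a test of the difference itself. Between after and before OHT, the differences were -0.68 for Rif1, -1.28 for Xist and 0.12 for X-linked against autosomal genes. In the same comparison list medians were 1.79 for two-cell-like, 0.81 for germline and -0.20 for heterochromatin and KAP1 silencing genes. Between EB and mESC they were 0.43 for Rif1, -0.79 for Xist and 0.35 for X-linked against autosomal genes. List medians were -0.61 for formative, 2.73 for two-cell-like, 0.68 for germline and -0.19 for imprinted genes. With an estimated correlation all 7 list and both X-linked calls ended, at adjusted p = 0.426 for the 3 lists after OHT, 0.197 for formative and for two-cell-like, 0.591 for germline and 0.453 for imprinted genes in EB, and 0.24 and 0.0855 for X-linked genes. Xist between EB and mESC missed the threshold in DESeq2 (adjusted p = 0.0507) and without KO mESC replicate 3 (-0.51, adjusted p = 0.0820).

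6394 genes differed between the Rif1F/F and WT lines before deletion, a difference the design attributes to no treatment. Gain or loss of a whole autosome throughout a pair of lines is argued against, since the autosome farthest from 0, chromosome 16, had a median of -0.0718. Gain or loss of an autosome in a small part of the cells was not tested. Neither was X loss in part of the F/F cells, and the X had a median of -0.11. Partial deletion before OHT may contribute and cannot be told apart from other line differences, since the share of genes at least 2-fold apart that were further apart after OHT followed how they were picked: 25.6% (95% Clopper-Pearson interval 23.5 to 27.8) of the 1630 picked before OHT and measured in the same libraries, and, measured in the pair of lines not used for picking among genes of at least 1 CPM on average, 27.8% and 30.8% picked before OHT, 64.5% and 68.6% picked after it and 49.1% and 45.9% picked on the mean of both. Rif1 itself was lower in F/F by -0.49. Segments of different strain origin cannot be told apart from other line differences either: genes at least 2-fold apart lay within 10 genes of each other 1.40 times as often as chance, against 1.42 for an equal number from WT EB against mESC (difference -0.0200, SE 0.06) and 1.09 for all such genes, and the prediction did not name an equal number.

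X-linked genes were higher in KO than in WT EB. GC content, length or expression level are argued against as the whole cause, since X-linked genes lay 0.30 (0.25 to 0.36 over 1000 draws) above autosomal genes matched on them, against 0.34 unmatched. Loss of an X chromosome in part of the WT EB cells is argued against, since it would raise escape genes with the rest, and their median was -0.0287 against 0.32 for other X-linked genes, at the 0.23rd percentile of 10000 random X-linked sets. These sets were not matched on expression, and the value in EB includes line differences. Before OHT, among the named escape genes, 1810030O07Rik, Shroom4 and Ddx3x were lower in F/F, by -0.64, -0.38 and -0.36, and Kdm6a higher by 0.56. Line differences common to mESC and EB cancel in the EB against mESC difference. There the escape median was -0.02 without WT mESC replicate 1, against 0.35 for X-linked genes with all libraries. Slower exit from the naive state calls for a KO change from mESC to EB between 0 and the -0.17 of WT, and the KO value of 0.27 counts against it, but it stays open because condition and flow cell cannot be told apart. The deletion of Rif1 stays open: with the difference before deletion (-0.11) taken off, X-linked genes lay 0.45 above autosomal genes in EB (adjusted p = 6.7e-13, and adjusted p = 0.0747 with an estimated correlation), a difference that also holds how each line differentiates.

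Two-cell-like genes were higher in KO than in WT EB. Reads shared between near-identical copies are argued against as the whole cause, since the 6 members sharing under 10% of their 50-base words had a median of 4.06 and all 6 were higher. Slower exit from the naive state calls for levels in KO EB between those of KO mESC and WT EB, and 29 of 32 genes above every library of both count against it, but it stays open because condition and flow cell cannot be told apart. A line difference present before deletion remains open: 2 of 32 genes were higher before deletion against 31 in EB, and the difference between these effects was called higher for 11 and lower for 0 (list adjusted p = 5.5e-19, and adjusted p = 0.144 with an estimated correlation). The deletion of Rif1 stays open too, since that difference also holds how each line differentiates.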

How the results depend on the processing

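The GC correction, the block with it, the block in list tests, removal of Rn45s, Lars2 and Rpph1, the estimated correlation for X-linked genes and every alternative of the correlation between mESC and EB were chosen after seeing the data. Of the alternative values, 119 of 128 gene counts, 10627 of 11078 named-gene values and 114 of 125 X-linked medians kept their direction and side of the threshold (for counts, stayed within 1.5 times). Apart from Rif1, Xist and Tsix, the named genes were picked by their calls in the main fit. Their share therefore does not extend to other genes. The cause of the changes was not tested, except that leaving out a library leaves fewer samples, which are then assumed to vary like the other groups.

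Leaving out 1 library at a time, genes called in KO against WT mESC numbered 4125 (without KO replicate 4) to 6544, and in the genotype by OHT difference 510 (without WT pre-deletion replicate 1) to 2540 (without WT mESC replicate 2), with 2218 when no low-count filter was used and 705 with only the groups compared. Xist in KO against WT mESC ranged from -0.86 to -0.35, the latter without KO replicate 4. Tsix in the genotype by OHT difference ranged from -0.30 to 0.19. From KO mESC to KO EB Tsix ranged from -0.15 to 0.23, and was -0.0153 with the GC trend taken out and -0.0151 with the block as well. Rif1 in WT from before to after OHT ranged from -0.19 to 0.00756. The X-linked median in KO against WT mESC ranged from -0.0226 (without KO replicate 3) to 0.0434. With an estimated correlation the X-linked calls in EB (0.34), before deletion (-0.11) and from KO mESC to EB (0.27), and in the genotype by OHT (0.12) and EB against mESC (0.35) differences, ended, and 1 list call was left of 40. The correlation of mESC and EB effects was 0.256 with no low-count filter and 0.336 to 0.408 leaving out 1 library.

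With line as a block, 579 of 584 named-gene values kept direction and call and 41 list calls passed. Xist from F/F to KO mESC (-0.28, adjusted p = 0.0240) and the feeder list from WT mESC to EB (adjusted p = 0.0440) passed with the block and not without it. Calls ended for Rnf168 (-0.39) and Pdk1 (-0.33) in the genotype by OHT difference and for Tsx (-0.58) and 5530601H04Rik (0.32) from F/F to KO mESC, and the block changed no other call. With the GC trend taken out, trophoblast genes passed in KO against WT EB (adjusted p = 0.0298), mesendoderm genes and p53 targets in the difference between EB and mESC effects (adjusted p = 0.0242 for both), and the X-inactivation centre in WT after against before OHT (adjusted p = 0.0412). With 2 libraries per group, 50.7% of simulated 1.5-fold differences were recovered in the genotype by OHT test, which limits what that test can show.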

Other observations

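The gene families tested here, and the rerun without 1 library, were chosen after seeing the data.

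Of 267 families named by a shared symbol stem, histone genes (Hist) were higher in KO than in WT mESC in 54 of 58 members and lower in 0, with a median of 1.11 (adjusted p = 2.4e-10, and adjusted p = 0.982 with an estimated correlation). WT mESC replicate 1 had a median histone level of 12.7 CPM against 31.0 to 67.3 in the other libraries, and without it 45 were higher, with a median of 0.63. In the difference between EB and mESC effects 35 were lower and 1 higher, with a median of -0.84 (adjusted p = 1.4e-04, and adjusted p = 0.995 with an estimated correlation), and without that library 23 and 2, with a median of -0.47.

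Rhox homeobox genes, an X-linked cluster used in germ cells and trophoblast, were higher in KO than in WT EB in 13 of 14 members, with 0 lower and a median of 2.82 (adjusted p = 4.9e-08, and adjusted p = 0.870 with an estimated correlation). Between the genotype effects after and before OHT, 8 were higher and 0 lower, with a median of 2.98 (adjusted p = 1.4e-11, and adjusted p = 0.787 with an estimated correlation). Olfactory receptor genes (Olfr) were higher in KO EB in 19 of 45 members and lower in 0, with a median of 1.07 (adjusted p = 1.6e-05, and adjusted p = 0.870 with an estimated correlation). Sequence shared within these families was not measured.

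Levels of Meg3 in WT were 31.5 CPM before deletion, 16.8 ± 1.89 CPM in mESC and 275 ± 4.87 CPM in EB, against 171, 132 ± 15.8 and 289 ± 7.57 CPM in the Rif1F/F lines. Rian of the same cluster stood at 34.5 CPM in WT mESC and 198 CPM in KO mESC, and at 454 and 513 CPM in EB.

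Log2 fold changes trended with transcript GC content across 16960 genes, which are not independent replicates. Spearman's rho was 0.16 for KO against WT mESC, -0.23 in EB and -0.01 before deletion. The median went from -0.10 in the 20% of genes lowest in GC to 0.18 in the 20% highest in mESC, and from 0.07 to -0.17 in EB.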
